A study of Mus musculus with 9 samples.

How the data were processed

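Total RNA of mouse LLC1 cells kept with Th0, Th9 or Th17 T cells was measured in 9 libraries (3 groups of 3), per the labels' protocols after 24 h at 1 T cell per LLC1 cell and after CD4-positive cells were sorted away. Libraries were made from 1 µg of total RNA with a stranded SMARTer kit for mammalian RNA, and RNA was isolated with a column kit that digests DNA, per the labels' protocols. STAR 2.4.0a, featureCounts 1.4.5-p1 of the Subread package and DESeq2 1.62, with builds mm10 and GRCm38, are named per the submitters' processing notes, which give no order or role to them. Whether counting used the strand is not stated, so overlapping and antisense genes can share reads, as can paralogs.

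The authors deposited 2 tables of whole-number scores per gene, which are read counts divided by 1 size factor per library and rounded, normalized on their own for the table with Th9 and for the table with Th17. This was checked on the values: the 3 Th0 libraries, which stand in both tables, differed between them by 1 factor per library (1.02845, 1.02164 and 1.02619), with 3, 2 and 0 of 18022 shared genes off by more than 1. Each column also used whole numbers at regular steps, which gave its size factor. The tables list 18816 and 18511 genes (19305 in either), and genes with few reads in every library are not listed. Of the 19305 Ensembl IDs, 19247 were found in GENCODE M21, 19244 on the same chromosome and strand and overlapping, and 16332 with identical coordinates. Symbols and coordinates are those of the tables. No column of values per sample was left unused (0).

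Approximate reads were obtained as the deposited value times the size factor. Between 65.0% (Th17 replicate 2) and 100% of a library's values allow only 1 read number, and the Th0 reads from both tables were equal within 1 read for 99.6%, 99.95% and 99.95% of genes. Depth was the sum of these reads, 13466955, 15336482 and 12718847 for Th0, 14622039, 13616738 and 13537298 for Th9, and 13779098, 17504219 and 15505668 for Th17. The spread between libraries of a group was the chi-square of approximate reads per degree of freedom.

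Th9 and Th17 were each compared with Th0 within their own table. limma-trend (limma 3.58.1, R 4.3.3; lmFit and eBayes with a trend) was run on log2(value + 1) for genes with a mean of at least 10 over the 6 libraries, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as a call. For Th17 against Th9 a count-based test had been chosen before the data were examined. As the values are rounded normalized counts and not counts, limma-trend was used instead of edgeR, on log2(value + 1) of approximate reads brought to 1 scale by TMM factors (trimmed by 30% and 5%), with all 9 libraries in the model. The condition set for this comparison, that reads could be recovered from both tables and that Th0 held the same reads in both, was met to within about 1 read. The overlap of both comparisons is given beside that of independent lists and beside 100 simulations of unchanged groups against shared controls.

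Gene lists (30) for EMT transcription factors, mesenchymal and matrix genes, epithelial genes, proteases and adhesion genes, TGF-beta response, interferon-gamma and type I interferon response, MHC class I and II, NF-kB and IL-17 targets, STAT3 targets, STAT5 and STAT6 targets, G1/S, G2/M, p53 targets, hypoxia and glycolysis, cholesterol, the unfolded protein and integrated stress response, heat shock and immediate early genes, ribosomal proteins, mitochondrially encoded genes, histones, nuclear long non-coding RNAs, T cell markers, Th1, Th9, Th17 and regulatory T cell genes, markers of B, myeloid, NK and CD8 T cells, and red cell genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Calls were counted with adjustment over all genes and over the list alone, and the latter are given in the comparisons with Th0 where they differ. Lists with under 3 tested members were not tested, which held for MHC class II and red cell genes in Th9, and for red cell, Th1 and Th9 genes in Th17. In Th17 against Th9, red cell genes were not tested. KEGG pathways of 10 to 300 genes were tested in the same way.

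The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction (8 for Th17 against Th9) with the largest called change, a mean of at least 50, no overlap between groups and a plain symbol, up to 4 members with the smallest adjusted p of each list that passed or had at least 3 calls, and always Cdh1, Cdh2, Vim, Fn1, Snai1, Snai2, Twist1, Zeb1, Zeb2, Cd3e, Cd4, Ptprc, Il9, Il17a and Ifng. Other genes that the text names were chosen after their values were seen: Axl, Itgav, Col1a1, Acta2, S100a4, Ncam1, Sparc, Lgals1, Timp2, Itga3, Mmp14, Il6st, Calr, Psme1, Pdia4, Sdf2l1, Xbp1, Sesn1, Bnip3, Bub1, Gata3, Irf4, Maf, Rora, Cd14, Lyz2, Ctsd, Nfkb2, Epcam, Ifitm3, Slc7a5, Emilin1, Lig1, the T cell receptor and immunoglobulin genes, genes of the figures that no other rule took, and, in Th17, Ccl2 and Myc.

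The fit of each comparison was tested on simulated counts with 200 changed genes at the real means and library sizes, 50 at each fold. For Th17 against Th9 the recovery of approximate reads from 2 rounded tables was not part of this simulation. On 14468 genes for Th9 against Th0, 28%, 80%, 98% and 100% of genes changed by 1.25, 1.5, 2 and 4-fold were called, and 2.96% of calls were unchanged genes. For Th17 against Th0 (14350 genes) the shares were 38%, 82%, 96% and 100%, with 6.74% of calls unchanged, and for Th17 against Th9 (14432 genes) 32%, 78%, 94% and 100%, with 5.29%. The simulation gave every library the same spread, unlike the Th0 libraries, of which replicate 1 stood apart. It also gave all genes of a comparison the same dispersion (spread beyond counting error; 0.0051, 0.0043 and 0.0039 in the order above). These shares therefore do not describe the power or the false calls of the real comparisons.

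Alternatives were another amount added before the log (0.5 or 5), no filter or a mean of at least 50, TMM on top of the deposited values, the same total per library, array weights, the replicate number as a block and each library left out. For Th17 against Th9 they were log2 CPM (counts scaled to library size), median-of-ratios size factors, no filter, only the 6 Th9 and Th17 libraries, the block and each library left out. After the data were seen, removal of GC content and transcript length trends per library (loess, span 0.4) and the same total without mt-Rnr1, mt-Rnr2 and Gm26917 were added. Recovery of reads and drawing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.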

Results

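Lewis lung carcinoma (LLC1) cells, a mouse lung cancer line, were kept for 24 h with T cells labelled Th0, Th9 or Th17, touching each other, at 1 T cell per LLC1 cell. CD4-positive cells were then sorted away, and total RNA of the cells that remained was sequenced. By its title, the series asks whether Th9 and Th17 cells push lung cancer cells into an epithelial-mesenchymal transition (EMT), in which epithelial cells take on mesenchymal traits, and so favour metastasis. There were 3 groups of 3 libraries. Values are normalized counts per gene, rounded to whole numbers, in 2 tables of 6 libraries that share the Th0 libraries, 1 with Th9 (18816 genes) and 1 with Th17 (18511 genes). Fold changes are differences of mean log2(value + 1), coordinates are those of GRCm38 (mm10), and levels are mean ± SD with n = 3 libraries per group. The labels do not say whether the libraries of a group are separate cultures, so p-values measure the spread between these samples.

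The approximate number of assigned reads was 13466955, 15336482 and 12718847 in Th0 replicates 1 to 3. It was 14622039, 13616738 and 13537298 in the Th9 libraries, and 13779098, 17504219 and 15505668 in the Th17 libraries. Th0 replicate 1 stood apart from every other library. In it, 31.1% of the reads fell on the mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 and the non-coding gene Gm26917, against 16.6% and 14.9% in the other Th0 libraries, 16.1% to 18.6% in the Th9 libraries and 20.7% to 21.8% in the Th17 libraries. The spread between libraries of a group, as chi-square per degree of freedom (1 is counting error alone), was 83.3 and 95.1 for Th0 replicate 1 against replicates 2 and 3, 7.89 between those 2, 2.30 to 7.43 within Th9 and 4.38 to 6.61 within Th17. In a principal component analysis the first component (64.1% of the variance) parted Th9 from Th0, whereas in the table with Th17 the first component (35.6%) set Th0 replicate 1, at -41.8, apart from the 5 other libraries, at 3.09 to 15.6.

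Th9 against Th0 asks what contact with Th9 cells changed in the cells that passed the sort. Chemokine and other NF-kB target genes rose most clearly. Ccl2, which draws monocytes, went from 196 ± 33.1 to 3861 ± 351, a 19.7-fold rise. Cxcl1, which draws neutrophils, went from 99.7 ± 17 to 1147 ± 159.7 (11.4-fold), and Nfkbia, the inhibitor that NF-kB itself induces, from 322 ± 1.53 to 1545 ± 186 (4.76-fold). T cell transcripts rose as well: Cd3g, a chain of the T cell receptor complex, went from 5 ± 3 to 317 ± 54.9. Among the genes that fell were Thbs1 (thrombospondin 1, from 1246 ± 154 to 164 ± 13.2) and Col3a1 (type III collagen, from 19447 ± 507 to 7539 ± 325). The EMT transcription factor genes moved little: Snai2 rose 1.65-fold, Zeb2 rose 1.32-fold, and Snai1, Twist1 and Zeb1 did not pass the test.

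Of 24 T cell marker genes tested in Th9 against Th0, 21 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 3.68 (camera adjusted p = 3.7e-18, and adjusted p = 0.205 with an estimated correlation). Cd3g (ENSMUSG00000002033, chromosome 9, positions 44969572 to 44980431) had a log2 fold change of 5.85 (SE 0.34, adjusted p = 4.3e-07). Cd3e, another chain of the receptor complex, had 4.0 (SE 0.36, adjusted p = 1.0e-05). Ptprc (CD45, found on all white blood cells) had 4.45 (adjusted p = 6.9e-05). Themis, a thymocyte signalling gene, went from 0.333 ± 0.577 to 50.3 ± 7.51. Cd4 itself was at 12 ± 5.29 to 21 ± 3.46 and did not pass the test (log2 fold change 0.82, adjusted p = 0.114). The 3 tested Th1 and effector genes rose (3 adjusted over the list alone), with a median of 3.42 (adjusted p = 2.8e-04, and adjusted p = 0.197 with an estimated correlation). They were Gzmb (granzyme B, 4.94), Tnfrsf9 (the receptor 4-1BB, 3.42) and Il12rb2 (a chain of the interleukin 12 receptor, 1.87). Of 7 regulatory T cell genes, Il2ra (5.81) and Ikzf2 (1.18) rose and Nrp1 fell (-0.43, adjusted p = 0.0398), while Foxp3 did not pass (0.57, adjusted p = 0.294). That list as a whole did not pass (median 0.38, adjusted p = 0.0714). Nrp1 lost its call without any 1 of the 5 libraries other than Th0 replicate 1 (adjusted p up to 0.141, without Th9 replicate 1). Of 4 Th9 genes, Gata3 and Irf4 rose (list median 1.27, adjusted p = 0.189), and of 4 Th17 genes, Maf and Rora rose (0.91, adjusted p = 0.206). Rora lost its call without Th9 replicate 1 (adjusted p = 0.0586). Il9, Il17a and Ifng were not listed. Among 7 markers of B, myeloid, NK and CD8 T cells Cd14 rose and Lyz2 fell (adjusted p = 0.981), and Cd14 lost its call without Th0 replicate 3 (0.0537), Th9 replicate 1 (0.0716) or Th9 replicate 2 (0.0563). That list's median was -0.01, its camera direction was up, and its median turned to 0.21 with the same total per library and to 0.03 with the same total without the 3 RNA genes.

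The other largest rises were in genes with a mean of 9 or less in Th0, many of them lymphocyte genes. Fam46a went from 0.667 ± 0.577 to 104 ± 28.3 and Trdc, the constant gene of the T cell receptor delta chain, from 1.67 ± 1.53 to 108 ± 34.5 (adjusted p = 9.5e-06). P2ry10, a lymphocyte receptor gene, went from 1.33 ± 0.577 to 124 ± 19.5. Thy1, a T cell surface gene that the mesenchymal list also holds, had a log2 fold change of 5.36, Ctla2a 5.35, the calcium pump gene Atp2b4 5.30, the inhibitory receptor gene Ctla4 5.01 and the T cell chromatin organiser Satb1 4.60. C3, the central complement component, which is not a T cell marker, went from 4.33 ± 2.08 to 294 ± 37.0 (adjusted p = 1.8e-07). The T cell markers and the inflammatory genes were high in the same 3 libraries.

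**Figure D1:**
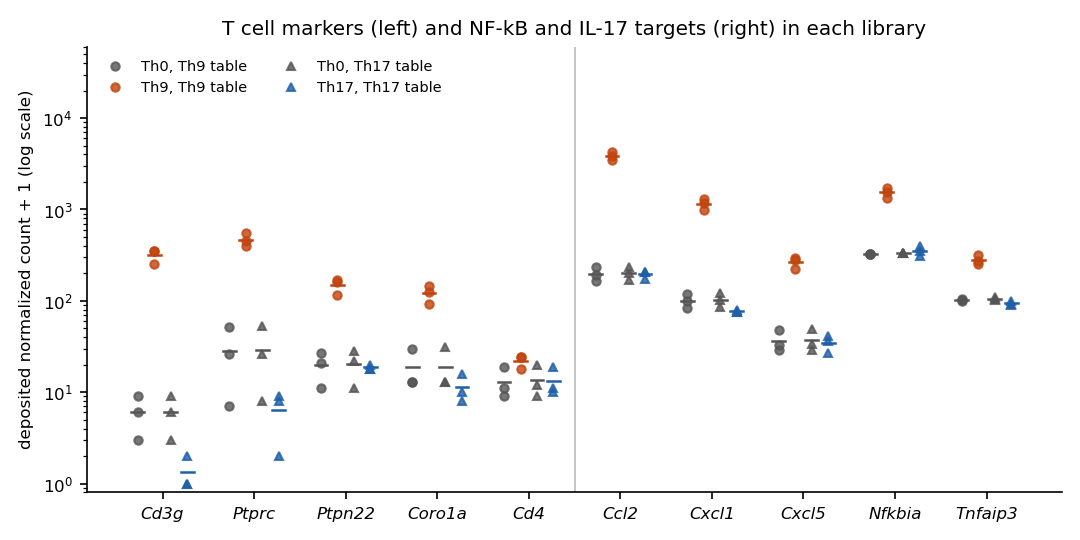
Deposited normalized count + 1 on a log axis for 5 T cell genes (left) and 5 NF-kB target genes (right), with a point per library, a bar at each group mean, circles for the table with Th9 and triangles for the table with Th17. The T cell genes other than Cd4 and the NF-kB genes are high in the 3 Th9 libraries and not in the Th17 libraries: Ccl2 averaged 3861 in Th9, 196 in Th0 in the same table and 194 in Th17.

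All 16 tested NF-kB and IL-17 target genes rose in Th9 (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.88 and a camera adjusted p of 8.4e-20. This was the 1 list that kept its call with an estimated correlation (adjusted p = 0.0255). Ccl2 (ENSMUSG00000035385, chromosome 11, positions 82035571 to 82037453) had a log2 fold change of 4.30 (SE 0.12, adjusted p = 1.1e-09), Cxcl1 3.52 (SE 0.14, adjusted p = 1.2e-08), Nfkbia 2.25 (adjusted p = 3.2e-08) and Traf1, a signalling adaptor that T cells also express, 4.25 (adjusted p = 6.8e-07). Of 13 STAT3 target genes, 11 rose and 1, Il6st, fell (11 and 1 adjusted over the list alone; median 0.92, adjusted p = 1.3e-08, and adjusted p = 0.197 with an estimated correlation). Il6st lost its call with the same total per library (adjusted p = 0.119). Among them were Osmr, the oncostatin M receptor (2.36), Cebpd (2.53), the growth regulator Myc, at 4630.3 ± 299 to 12192 ± 1697 (1.39), and the cytokine gene Lif (1.2). Of 5 STAT5 and STAT6 targets, 3 rose (4 adjusted over the list alone; median 1.55, adjusted p = 0.00351, and adjusted p = 0.197 with an estimated correlation): Il2ra, Socs2 (1.55) and Il13ra1 (1.6). Il13ra1 lost its call without Th0 replicate 3 (adjusted p = 0.0696), and Il4ra, at 0.25, gained one without Th0 replicate 1 (adjusted p = 0.00907), with array weights (0.00231), with the same total per library (0.0397) and with the same total without the 3 RNA genes (0.0493). Il2ra is also in the regulatory T cell list, and T cell markers rose in the same 3 libraries.

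Antigen presentation genes rose in part. Of 16 MHC class I genes, 9 rose and 2, Calr and Psme1, fell (9 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.00226, and adjusted p = 0.197 with an estimated correlation). Psme1 lost its call with the same total per library (adjusted p = 0.197) and without any 1 of the 5 libraries other than Th0 replicate 1 (up to 0.160, without Th0 replicate 3). Nlrc5, the activator of the class I genes, had a log2 fold change of 1.35, H2-K1 1.07, H2-T23 1.01 and B2m 0.86, although related class I genes can share reads. T cells express class I genes as well, and T cell markers rose in the same 3 libraries. The interferon lists did not pass. Of 10 interferon-gamma response genes, Irf8 (1.45) and Socs1 (0.85) rose, Irgm1 fell (-0.57) and Cd274 did not pass (0.54, adjusted p = 0.108, but 0.0387 with array weights), with a list median of 0.12 (adjusted p = 0.630). Socs1 lost its call without Th0 replicate 3 (adjusted p = 0.0870), Th9 replicate 1 (0.111) or Th9 replicate 2 (0.102). Of 10 type I interferon response genes, Bst2 (0.81) and Oas3 (1.34) rose and Usp18 (-0.96) and Xaf1 (-0.95) fell (2 and 3 adjusted over the list alone; median -0.14, adjusted p = 0.730). Usp18, Xaf1 and Oas3 did not keep their calls with each library left out, which also leaves fewer samples. Xaf1 lost its call without any 1 of the 6, with adjusted p from 0.0583 without Th0 replicate 2 to 0.113 without Th9 replicate 3. Usp18 lost it without Th0 replicate 2 or 3 or Th9 replicate 1 or 2 (0.0957 at most, without Th9 replicate 1), and Oas3 without Th0 replicate 1 or 2 or Th9 replicate 2 (0.101 at most, without Th9 replicate 2). Oas3 also lost it with array weights (0.0763), and Xaf1 with the same total per library (0.0566) and with the same total without the 3 RNA genes (0.0531).

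The genes the series title asks about moved in both directions in Th9. Of 9 EMT transcription factor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a list median of 0.19 (adjusted p = 0.531). Snai2 (ENSMUSG00000022676, chromosome 16, positions 14705852 to 14709395), a repressor of epithelial genes, went from 449 ± 86.9 to 735 ± 49.7 (log2 fold change 0.73, SE 0.12, adjusted p = 0.00119), and Zeb2 from 2454 ± 189 to 3237 ± 129 (0.40, adjusted p = 0.00522). Tcf4 fell by 0.32 on the log2 scale (adjusted p = 0.0192). Tcf4 lost its call with the same total per library (adjusted p = 0.307) and without Th0 replicate 3 (0.0579), Th9 replicate 1 (0.117) or Th9 replicate 2 (0.107). Snai1 was at 0.39 (adjusted p = 0.194), Twist1 at -0.18 (0.392), Prrx1 at 0.22 (0.171) and Zeb1 at -0.04 (0.746, 0.07 with the same total per library). Of 21 mesenchymal and matrix genes, 5 rose and 7 fell (6 and 7 adjusted over the list alone; adjusted p = 0.404). The list's median was -0.08, its mean 0.02 and its camera direction down, and the median turned to 0.03 with the same total per library. The mean was above 0 only through Thy1, the highest member at 5.36. Thy1 is a T cell surface gene, and T cell markers rose in the same 3 libraries. Among the genes that rose were Thy1, Spp1 (osteopontin, 0.69), Axl and Itgav. Those that fell were Col3a1 (ENSMUSG00000026043, chromosome 1, positions 45311538 to 45349706; -1.37, SE 0.10, adjusted p = 2.6e-06), Col5a1 (-1.36, from 7214 ± 573 to 2805 ± 113), Col1a1, Acta2 (smooth muscle actin), S100a4, Ncam1 and Sparc. Itgav lost its call without Th0 replicate 3 (adjusted p = 0.0931) or Th9 replicate 1 (0.199), 2 (0.0890) or 3 (0.139), with no filter (0.0542), with GC content and transcript length trends removed (0.168) and with the same total per library (0.0609), as Sparc did with that total (0.0784). The mesenchymal markers Vim (-0.08, adjusted p = 0.812), Cdh2 (-0.13, 0.542) and Fn1 (-0.25, 0.16) did not pass over all libraries. Without Th0 replicate 1, Vim (-0.25, adjusted p = 0.00886), Cdh2 (-0.31, 0.0108), Fn1 (-0.29, 0.00209) and Twist1 (-0.36, 0.00171) were called lower, and Snai1 (0.56, 0.0321) higher. With array weights, over all 6 libraries, Cdh2 (-0.22, 0.0393), Fn1 (-0.26, 0.0125) and Twist1 (-0.32, 0.00408) were called lower and Snai1 (0.54, 0.0127) higher, and with the same total without the 3 RNA genes Prrx1 was called higher (0.27, 0.0374). Of 8 epithelial genes, the keratin gene Krt8, at 2147 ± 408 to 1087 ± 153 (-0.97, adjusted p = 3.2e-04), and the tight junction gene Tjp1 (-0.42, 0.023) fell and Pkp3, a desmosome gene, rose (0.57, 0.0296), the same counts as adjusted over the list alone (median -0.37, adjusted p = 0.199). Krt18 was at -0.32 (adjusted p = 0.0899) and was called without Th0 replicate 1 (-0.49, 1.2e-05), with array weights (-0.48, 3.4e-05) and with the replicate block (0.0236). Tjp1 and Pkp3 each lost their call without any 1 of the 5 libraries other than Th0 replicate 1 (adjusted p up to 0.141 for Tjp1, without Th9 replicate 1, and up to 0.0990 for Pkp3, without the same library), and Tjp1 also with the same total per library (0.214). Cdh1 and Epcam were not listed.

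**Figure D2:**
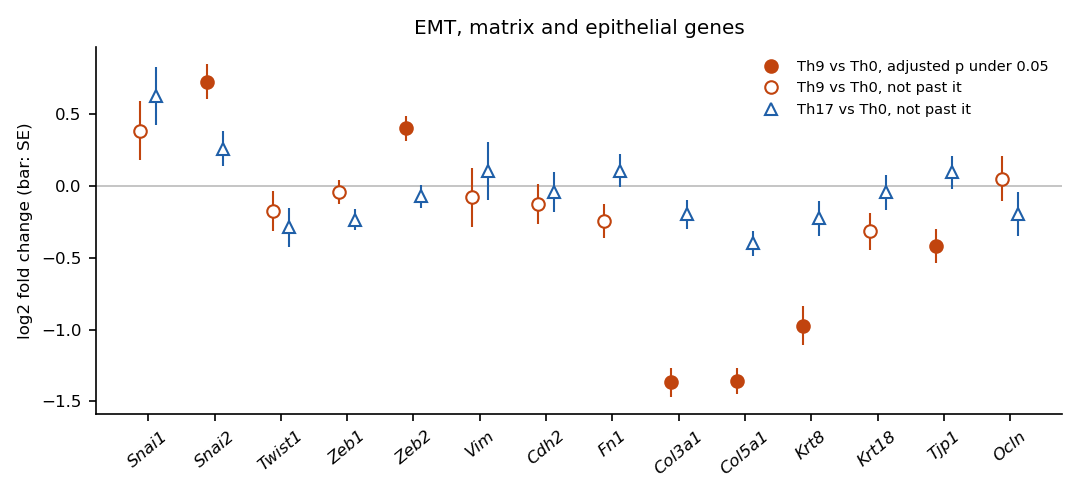
Log2 fold change ± SE against Th0 (vertical axis) of 14 EMT, matrix and epithelial genes in Th9 and in Th17, with filled points at an adjusted p under 0.05. In Th9, Snai2 (0.73) and Zeb2 (0.40) are higher and Col3a1 (-1.37), Col5a1 (-1.36), Krt8 (-0.97) and Tjp1 (-0.42) lower, Tjp1 not with the same total per library, and in Th17 no point is filled.

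Genes of invasion and of the TGF-beta response were mixed. Of 23 proteases, inhibitors and adhesion genes, 12 rose and 4 fell (12 and 5 adjusted over the list alone; median 0.28, adjusted p = 0.00429, and adjusted p = 0.330 with an estimated correlation). The call of that list ended among genes with a mean of at least 50 (adjusted p = 0.0653). Here too, T cell markers rose in the same 3 Th9 libraries. The matrix proteases Mmp3, from 112 ± 13.3 to 1089 ± 45.5 (3.27, SE 0.11, adjusted p = 3.5e-09), Mmp13 (3.52) and Mmp9, from 0.667 ± 0.577 to 59.7 ± 3.21, rose, as did Cd47 (0.82). Lgals1, Timp2, Itga3 and Mmp14 fell. With the same total per library Timp2 (adjusted p = 0.0702), Itga3 (0.382) and Mmp14 (0.406) lost their calls. Mmp14 also lost its call without any 1 of the 5 libraries other than Th0 replicate 1 (up to 0.144, without Th0 replicate 3), and Itga3 without Th0 replicate 2 (0.0574) or 3 (0.0795) or Th9 replicate 1 (0.175) or 2 (0.0914). Of 17 TGF-beta response genes, 6 rose and 4 fell (7 and 5 adjusted over the list alone; median 0.21, adjusted p = 0.210). Ltbp2 (2.46), Tgfb1, the cytokine itself (1.16), and the repressor gene Skil (0.62) rose, and the matrix gene Tgfbi fell (-1.90).

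The list of the unfolded protein and integrated stress response was higher and the G1/S and G2/M lists lower in Th9, none of them with an estimated correlation. T cell markers rose in the same 3 Th9 libraries, and reads of T cells were not set apart for these lists. Of 18 genes of the unfolded protein and integrated stress response, 12 rose and 3, Pdia4, Sdf2l1 and Xbp1, fell (12 and 3 adjusted over the list alone; median 0.69, adjusted p = 1.3e-05, and adjusted p = 0.310 with an estimated correlation). Slc7a11, the cystine transporter, went from 297 ± 29.1 to 2165 ± 145 (2.86, SE 0.09, adjusted p = 3.5e-09). Trib3 had 2.01, Chac1 2.67 and Vldlr 1.34. Pdia4, Sdf2l1 and Xbp1 lost their calls with the same total per library (adjusted p = 0.0718, 0.0921 and 0.102). Xbp1 also lost its call without Th9 replicate 1 (0.0527), and Sdf2l1 without Th0 replicate 2 (0.0548), Th0 replicate 3 (0.0728), Th9 replicate 1 (0.0693) or Th9 replicate 2 (0.0696). Of 15 p53 target genes, 9 rose and Sesn1 fell (9 and 1 adjusted over the list alone; median 0.37, adjusted p = 7.7e-04, and adjusted p = 0.197 with an estimated correlation), with Sesn2 at 1.42, Bbc3 at 0.80, Zmat3 at 0.55 and Eda2r at 0.49. Of 21 hypoxia and glycolysis genes, 8 rose and Bnip3 fell (10 and 3 adjusted over the list alone; median 0.24, adjusted p = 0.00714, and adjusted p = 0.473 with an estimated correlation), among them Vegfa (0.74), Hk2 (0.71), Ndrg1 (0.62) and Gapdh (0.55). Of 24 ribosomal protein genes, 6 rose (6 adjusted over the list alone; median 0.18, adjusted p = 0.00265, and adjusted p = 0.473 with an estimated correlation), such as Rps3 (0.43), Rps18 (0.40) and Rpl32 (0.44). Rpl32 lost its call without Th9 replicate 2 (adjusted p = 0.0525). Of 21 genes of G1/S and DNA replication, 12 fell and none rose (16 and 0 adjusted over the list alone; median -0.38, adjusted p = 3.2e-07, and adjusted p = 0.310 with an estimated correlation), such as Tyms (-0.78), Tk1 (-0.59), Cdc6 (-0.62) and Ccne2 (-0.92). Of 21 G2/M genes, 14 fell and Bub1 rose (16 and 1 adjusted over the list alone; median -0.37, adjusted p = 2.6e-06, and adjusted p = 0.330 with an estimated correlation), among them the survivin gene Birc5 (-0.68), Cenpf (-0.58), Cdk1 (-0.49) and Cenpe (-0.37). Cenpf (adjusted p = 0.0532), Cdk1 (0.0755) and Cenpe (0.184) lost their calls with the same total per library, and Cenpe without Th9 replicate 1 (0.0634). Bub1 lost its call without Th0 replicate 3 (0.0952), Th9 replicate 1 (0.108) or Th9 replicate 2 (0.107) and with GC content and transcript length trends removed (0.0533). Of 18 histone genes, 5 fell (5 adjusted over the list alone; median -0.23, adjusted p = 0.00676, and adjusted p = 0.473 with an estimated correlation), among them Hist1h1b (-0.79), Hist1h1e (-0.73), Hist2h2ac (-0.93) and Hist1h2bc (-0.56). That call ended with GC content and transcript length trends removed (adjusted p = 0.0700).

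The other lists did not pass in Th9. Of 20 cholesterol genes, Msmo1 (0.52) rose and 4 fell, among them Insig1 (-0.46) and Mvk (-0.46), with a median of -0.09 that turned to 0.02 with the same total per library (adjusted p = 0.210). Insig1 (adjusted p = 0.0570) and Mvk (0.140) lost their calls with that scaling, and Mvk without Th0 replicate 3 (0.139) or Th9 replicate 1 (0.102), 2 (0.0761) or 3 (0.0913). Of 14 heat shock and immediate early genes, Ier3 (1.23) rose and Egr1 (-1.0), Fos (-0.89) and Dnajb1 (-0.32) fell (2 and 3 adjusted over the list alone; median -0.11, adjusted p = 0.701). Fos (adjusted p = 0.0557) and Dnajb1 (0.296) lost their calls with the same total per library, and both also without any 1 of the 5 libraries other than Th0 replicate 1 (up to 0.137 for Fos, without Th0 replicate 3, and 0.151 for Dnajb1, without Th9 replicate 3). No gene passed among 9 mitochondrially encoded genes (median -0.13, adjusted p = 0.566) or 9 nuclear long non-coding RNAs (-0.06, adjusted p = 0.701, 0.05 with the same total per library). At an unadjusted p under 0.05, 5432 of all genes tested would pass.

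Among the largest falls in Th9, Ptn, the growth factor pleiotrophin (ENSMUSG00000029838, chromosome 6, positions 36714929 to 36810220), went from 221 ± 13.1 to 20.7 ± 3.51, a 10.3-fold fall (log2 fold change -3.37, SE 0.18, adjusted p = 2.3e-07). Thbs1 (chromosome 2, positions 118111876 to 118127133) was 7.52-fold lower (-2.91, adjusted p = 1.1e-08) and Syt13, a synaptotagmin, 10.2-fold. The scavenger receptor gene Scara5 (-3.07), Rab3il1 (-2.50), the hormone gene Stc1 (-2.04), Limch1 (-1.91), Enpp2, which encodes autotaxin (-1.87), the proteoglycan gene Ogn (-1.77) and the collagen VI genes Col6a1 (-1.77) and Col6a2 (-2.17) fell too.

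Of 14475 genes tested in Th9 against Th0, 1937 were higher and 1716 lower at an adjusted p under 0.05 (limma), and of these 513 and 260 changed by a factor of 2 or more. The 3 Th9 and 3 Th0 values did not overlap for 40.6% of the genes, where chance gives 10%. With the same total per library, 2251 were higher and 794 lower (73.9% higher, against 53%), and the median of all genes moved from -0.01 to 0.10. Many of the falls were lost with that scaling, but mostly through the 3 RNA genes that enter the total. Of the 1716 genes that were lower, 793 kept their call with the same total, and 1479 with these 3 genes left out of it. There were 2479 higher and 1516 lower with the same total without the 3 RNA genes, with TMM on top of the deposited values 1880 and 1858, and with array weights 3302 and 3326. Without Th0 replicate 1 there were 2594 higher and 2742 lower, without Th0 replicate 3 1465 and 1068, without Th9 replicate 1 1015 and 838, and without Th9 replicate 2 1131 and 947.

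Th17 against Th0 asks the same of contact with Th17 cells, and few genes passed. Alg3, a mannosyltransferase of N-glycan synthesis, went from 61.3 ± 10.5 to 177 ± 27.2, a 2.87-fold rise. Ly6e, a membrane protein gene that interferon induces, went from 2360 ± 405 to 5609 ± 875 (2.38-fold), Agpat1, an enzyme of phospholipid synthesis, from 585 ± 39.2 to 1144 ± 41.9 (1.95-fold), and Psat1, an enzyme of serine synthesis, from 2044 ± 131 to 3574 ± 160.2 (1.75-fold). Genes of cholesterol synthesis were higher as a group, but not with an estimated correlation (adjusted p = 0.977), and 3 of 20 were called. The immunoglobulin gene Ighm, which B cells express, was lower, at 103 ± 81.1 in Th0 and 2.67 ± 1.15 in Th17. Another immunoglobulin gene, Igkc, went the same way, from 24.3 ± 19.7 to 1.33 ± 1.53. Whether B cells left in the Th0 libraries gave these reads was not tested, so an effect of Th17 contact on LLC1 cells is not shown by them. Over all 6 libraries, none of the EMT, mesenchymal or epithelial genes listed beforehand passed, nor did T cell markers. Without Th0 replicate 1, 974 genes were higher and 1378 lower, some of the EMT, matrix and epithelial genes among them.

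Alg3 (ENSMUSG00000033809, chromosome 16, positions 20605451 to 20610768) had a log2 fold change of 1.52 (SE 0.17, adjusted p = 0.00291), Ly6e (ENSMUSG00000022587, chromosome 15, positions 74955051 to 74959905) 1.2525 (SE 0.14, 0.00291) and Agpat1 (ENSMUSG00000034254, chromosome 17, positions 34604262 to 34613449) 0.97 (SE 0.08, 0.00144). Psat1 had 0.81 (adjusted p = 0.00258), Scrn2 0.97 (0.00258) and Ighm -4.59 (0.00291). These 6 were the named genes that kept their call with each library left out. Tusc2 (1.27), Trappc1 (1.16), Fam189b (1.1), Wbp1 (1.08), Cript (0.98) and Higd2a (0.96) lost theirs without Th17 replicate 3, with adjusted p from 0.0544 for Tusc2 to 0.0614 for Higd2a, and all but Tusc2 also without Th17 replicate 1 (0.0573 for Trappc1 to 0.0686 for Higd2a). Dph1 (0.97) and the small RNA gene Rny3 (1.29) lost theirs without any 1 of the 5 libraries other than Th0 replicate 1 (up to 0.209 for Dph1 and 0.233 for Rny3, both without Th17 replicate 3), and Rny3 also with 0.5 added before the log (0.0501). Among the genes that fell were Sema3f, a secreted guidance factor (-0.89), Plaur, the urokinase receptor gene (-0.68), the zinc transporter gene Slc39a7 (-0.70), Zbtb10 (-0.72), Snhg20 (-0.92), Erdr1 (-0.78), Gpatch4 (-0.62), Ddx39 (-0.58), Hmgb3 (-0.54) and Incenp, a mitosis gene (-0.54). These 10 lost their call without Th0 replicate 3 (adjusted p from 0.0669 for Sema3f to 0.168 for Hmgb3) and without Th17 replicate 3 (0.0553 for Sema3f to 0.233 for Hmgb3). All but Gpatch4 also lost it without Th17 replicate 1 (0.0834 for Zbtb10 to 0.223 for Snhg20), all but Plaur without Th17 replicate 2 (0.0729 for Sema3f to 0.188 for Hmgb3), and Slc39a7 (0.0540), Ddx39 (0.0683) and Hmgb3 (0.0759) without Th0 replicate 2. Slc39a7 (adjusted p = 0.0577), Ddx39 (0.127), Hmgb3 (0.133) and Incenp (0.115) also lost theirs with the same total per library. Of the 34 named genes that were called, 34 kept their call without Th0 replicate 1, 28 without Th0 replicate 2 and 12 without Th0 replicate 3. Without Th17 replicates 1, 2 and 3, 8, 14 and 6 kept it.

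The cholesterol list was the 1 of 27 lists that passed in Th17. With no filter 4 lists passed, with array weights 3, with GC content and transcript length trends removed 2, without Th0 replicate 1 3, and with an estimated correlation 0. Of its 20 genes, 3 rose and none fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.26 (adjusted p = 3.6e-05, and adjusted p = 0.977 with an estimated correlation). They were Dhcr7, at 187 ± 15.7 to 281 ± 17 (0.58, adjusted p = 0.022), Sc5d (0.43, 0.0237) and Msmo1 (0.48, 0.0403). Nsdhl was at 0.46 (0.0527) and was called without Th0 replicate 1 (0.00978), with array weights (0.00183), among genes with a mean of at least 50 (0.0409), with TMM on top (0.0446) and with the same total without the 3 RNA genes (0.0250). Each of the 3 lost its call without Th0 replicate 3 or any 1 Th17 library, with adjusted p up to 0.181 for Dhcr7, 0.165 for Sc5d and 0.228 for Msmo1, all without Th17 replicate 3. With the same total per library Sc5d (0.0923) and Msmo1 (0.110) lost theirs, and Msmo1 did with GC content and transcript length trends removed (0.0545). Of 21 hypoxia and glycolysis genes, Tpi1 (0.53), Egln3 (0.49), P4ha1 (0.43) and Gapdh (0.42) rose (5 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.250). Their calls were lost with the same total per library (adjusted p from 0.0513 for Tpi1 to 0.133 for P4ha1) and without Th17 replicate 3 (0.118 for Tpi1 to 0.214 for P4ha1), Th17 replicate 1 (0.110 for Tpi1 to 0.173 for Gapdh) or Th0 replicate 3 (0.0765 for Tpi1 to 0.128 for Gapdh). All but Tpi1 also lost theirs without Th17 replicate 2 (0.0740 for Egln3 to 0.139 for P4ha1). Of 18 stress response genes, Psat1 and Herpud1 (0.50) rose and Ppp1r15a fell (-0.53), with 5 and 2 adjusted over the list alone (median 0.04, adjusted p = 0.486), and Dnajb9 was at 0.30 (0.105, but 0.0158 without Th0 replicate 1 and 0.0109 with array weights). Herpud1 and Ppp1r15a lost their calls without Th0 replicate 3 (adjusted p = 0.132 and 0.111), Th17 replicate 1 (0.139 and 0.139), Th17 replicate 2 (0.181 and 0.156) or Th17 replicate 3 (0.233 and 0.139), Ppp1r15a without Th0 replicate 2 (0.0518), and both with the same total per library (0.0745 and 0.122). Herpud1 also lost its call with the replicate block.

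The EMT genes did not pass in Th17. Of 9 EMT transcription factor genes none was called, but 2 were higher and 1 lower adjusted over the list alone (median 0.08, adjusted p = 0.909). Snai2 was at 460 ± 87.4 to 544 ± 21.7 (log2 fold change 0.26, adjusted p = 0.291) and Zeb2 at -0.07 (0.689). Snai1 was at 0.62 (0.141), Twist1 at -0.29 (0.286) and Zeb1 at -0.23 (0.14). Without Th0 replicate 1, Snai1 was called higher (0.81, adjusted p = 0.00719) and Twist1 (-0.47, 1.6e-04) and Zeb1 (-0.28, 0.00232) lower. So were Col3a1 (-0.18, 0.0281), Col5a1 (-0.35, 8.7e-04), Krt8 (-0.39, 2.9e-04), Krt18 (-0.21, 0.00873) and Ocln (-0.38, 0.0201) without that library, and Col5a1 without Th0 replicate 2 (-0.47, 0.0305). With array weights, over all 6 libraries, Snai1 (0.74, 0.00334) and Snai2 (0.26, 0.0313) were called higher and Twist1 (-0.40, 6.2e-04), Zeb1 (-0.27, 0.00231), Col3a1 (-0.19, 0.0450), Col5a1 (-0.41, 1.5e-04), Krt8 (-0.33, 0.00149), Krt18 (-0.20, 0.0405) and Ocln (-0.29, 0.0390) lower. Col5a1 was also called with no filter (0.0489), among genes with a mean of at least 50 (0.0430), with TMM on top (0.0491) and with the same total without the 3 RNA genes (0.0489). Of 20 mesenchymal and matrix genes none was called (0 and 1 adjusted over the list alone; median 0.07, mean and camera direction below 0, adjusted p = 0.994), with Vim at 0.10 (0.838), Cdh2 at -0.04 (0.906) and Fn1 at 0.11 (0.684). None of 10 epithelial genes was called (median -0.08, adjusted p = 0.893). Of 21 proteases and adhesion genes Ctsd rose and Plaur fell (3 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.250), and of 17 TGF-beta response genes none passed (0.10, adjusted p = 0.196). Ctsd lost its call with the same total per library (adjusted p = 0.0505) and without Th0 replicate 3 (0.0765), Th17 replicate 1 (0.122), Th17 replicate 2 (0.0986) or Th17 replicate 3 (0.127).

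Inflammatory lists did not pass in Th17 either. Of 12 NF-kB and IL-17 target genes Nfkb2 fell and none rose (2 and 0 lower and higher adjusted over the list alone; median -0.12, adjusted p = 0.250). Ccl2, with 201.3 ± 33.6 to 194 ± 18.8, was at -0.05 (adjusted p = 0.893). Nfkb2 lost its call without Th0 replicate 3 (adjusted p = 0.0803) or any 1 Th17 library (up to 0.122, without replicate 1), with the same total per library (0.134) and with GC content and transcript length trends removed (0.0697). Cxcl1 was called lower without Th0 replicate 1 (-0.54, 0.0221) and with array weights (-0.46, 0.0174). Of 13 STAT3 targets Myc rose (median 0.10, adjusted p = 0.126) but lost its call with the same total per library (0.0781) and without Th0 replicate 3 (0.0570) or Th17 replicate 1 (0.125), 2 (0.0708) or 3 (0.118). None was called among 3 STAT5 and STAT6 targets (median 0.43, adjusted p = 0.258), 11 interferon-gamma (0.07, 0.920), 9 type I interferon (-0.04, 0.893), 15 MHC class I (-0.08, 0.920) or 3 MHC class II genes (0 and 1 adjusted over the list alone; median 0.09 with a mean of -0.40, adjusted p = 0.742). The 8 tested T cell markers had none called (median -0.46, adjusted p = 0.196), with Ptprc at 28 ± 22.6 to 5.33 ± 3.79 (-2.09, adjusted p = 0.166) and Cd4 at 12.7 ± 5.69 to 12.3 ± 4.93 (0.99). Ptprc gained a call, as lower, with the replicate block. Likewise none passed among 3 Th17 genes (median 0.03, adjusted p = 0.909), 5 regulatory T cell genes (0.13 with a mean of -0.11, 0.941) and 6 markers of B, myeloid, NK and CD8 T cells (-0.27, 0.250). Of the cell cycle lists, Bub1 rose among 21 G2/M genes (0.03, 0.742) and none of 21 G1/S genes passed (-0.09, 0.196). Bub1 lost its call without Th0 replicate 3 (0.182) or any 1 Th17 library (up to 0.243, without replicate 1), with the same total per library (0.112) and with GC content and transcript length trends removed (0.0745). No gene passed among 14 p53 targets (1 and 1 adjusted over the list alone; adjusted p = 0.941), 14 heat shock genes (median 0.04, 0.941), 24 ribosomal protein genes (4 and 0 adjusted over the list alone; 0.05, 0.196), 9 mitochondrially encoded genes (0.24, 0.523), 18 histone genes (0 and 1 adjusted over the list alone; 0.08, 0.878) or 9 nuclear long non-coding RNAs (-0.13, 0.250). At an unadjusted p under 0.05, 2623 of all genes tested in limma would pass.

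Of 14342 genes tested in Th17 against Th0, 170 were higher and 56 lower at an adjusted p under 0.05 (limma), and of these 12 and 11 changed by a factor of 2 or more. The groups did not overlap for 23.4% of the genes, where chance gives 10%. The counts changed much with single libraries left out, which also leaves fewer samples, and no single library carried them. Without Th0 replicate 1 there were 974 higher and 1378 lower, without Th0 replicate 3 54 and 8, without Th17 replicate 1 15 and 4, without Th17 replicate 2 42 and 6, and without Th17 replicate 3 14 and 2. With the same total per library there were 119 and 20 (85.6% higher, against 75.2%), with array weights 1572 and 1789 (46.8% higher), and with the same total without the 3 RNA genes 345 and 102.

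The overlap of both comparisons asks which genes moved alike with either T cell type. Among 14113 genes tested in both, 122 were higher and 39 lower in both, which is 72.2% and 69.6% of the Th17 calls. Alg3 (1.64 in Th9 and 1.52 in Th17), Tusc2 (1.1 and 1.27), Psat1 (1.07 and 0.81), Agpat1 (0.91 and 0.97), Ly6e (0.75 and 1.2525), Myc (1.39 and 0.55) and Gapdh (0.55 and 0.42) rose in both. So did the interferon-induced gene Ifitm3 (1.2 and 0.59) and the amino acid transporter gene Slc7a5 (0.96 and 0.32). Sema3f (-1.48 and -0.89), Incenp (-0.99 and -0.54), the matrix gene Emilin1 (-1.21 and -0.46) and the DNA ligase gene Lig1 (-0.80 and -0.44) fell in both. In Th17, Ifitm3, Slc7a5, Emilin1 and Lig1 lost their calls without Th0 replicate 3 (adjusted p = 0.0874, 0.138, 0.111 and 0.157), Th17 replicate 1 (0.125, 0.248, 0.158 and 0.176), Th17 replicate 2 (0.0919, 0.241, 0.0919 and 0.238) or Th17 replicate 3 (0.0672, 0.233, 0.129 and 0.245). All but Ifitm3 also lost theirs with the same total per library (0.215, 0.144 and 0.215), and Slc7a5 (0.0636) and Lig1 (0.0626) without Th0 replicate 2. Emilin1 (0.0742) and Lig1 (0.0663) did so with GC content and transcript length trends removed, Slc7a5 with no filter (0.0530), and Slc7a5 (0.0999) and Lig1 (0.0507) with the replicate block. Independent lists of these sizes (1745 and 169 higher, 1716 and 56 lower) would share 20.9 and 6.81 genes. Unchanged groups simulated against shared controls shared 77.2 and 98 on average, with a median of 0, and as many as 122 higher in 6 and 39 lower in 7 of 100 simulations. Only 3 genes were higher in Th9 and lower in Th17, and 3 the reverse. The fold changes of both comparisons had a correlation across genes of 0.450 (Spearman 0.525), against a simulated mean of 0.627 and a simulated highest of 0.994. The covariance was 0.0627 against a simulated mean of 0.0383, a difference of 0.0243, and a simulated highest of 0.186 (genes are not independent replicates). Neither value lay above what unchanged groups with shared controls gave. The 3 controls were not split, since 1 part would keep fewer than 2 libraries, and the overlap may come from the shared controls in part or in full. Without Th0 replicate 1 the overlap was 573 higher and 967 lower, without Th0 replicate 2 163 and 63, without Th0 replicate 3 38 and 3, without Th9 replicate 1 72 and 29, and without Th9 replicate 2 73 and 30. Without Th17 replicate 1 it was 14 and 3, without Th17 replicate 2 35 and 2, and without Th17 replicate 3 13 and 1. With array weights it was 1026 and 1283, with the same total without the 3 RNA genes 245 and 71, and with the same total per library 12 genes were lower in both.

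**Figure D3:**
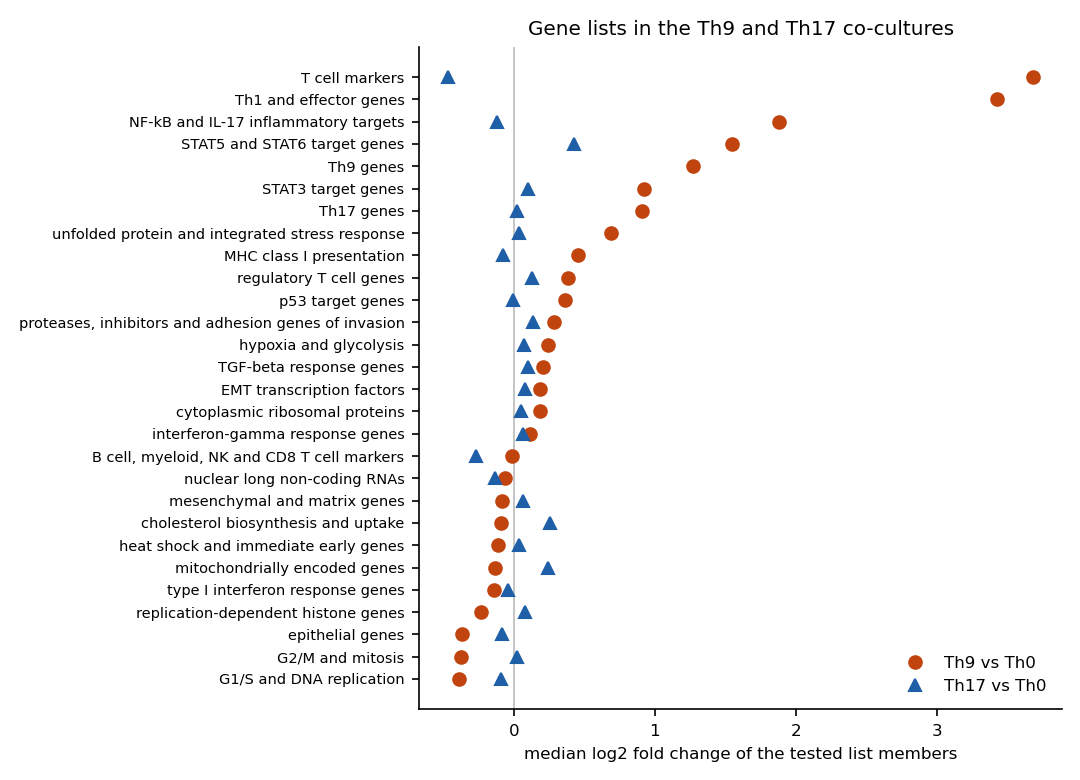
Median log2 fold change against Th0 (horizontal axis) of the tested members of each gene list in Th9 (circles) and in Th17 (triangles). The medians reach 3.68 for T cell markers and 1.88 for NF-kB and IL-17 target genes in Th9, over 24 and 16 members. In Th17 they are -0.46 and -0.12 over the 8 and 12 members tested there, so the medians of both are not over the same genes.

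Th17 against Th9 tests the difference between both effects directly, since the Th0 libraries cancel from the estimated difference. With all 9 libraries in the model they still enter the spread of each gene, and so the p-values. The tables were normalized separately by the authors, and their values were put on 1 scale for this comparison, so the levels given for it are not those deposited. T cell and inflammatory genes were lower in Th17: Cd3g was at 330.4 ± 56.5 to 0.274 ± 0.475 from Th9 to Th17, Ptprc at 485 ± 78.9 to 5.30 ± 3.78, C3 at 306 ± 39.1 to 2.67 ± 1.52 and Traf1 at 136 ± 22.2 to 1.26 ± 0.547. Among the genes higher in Th17 were Ptn at 21.5 ± 4.0 to 249 ± 40.9 (11.1-fold), Thbs1 at 171 ± 14.2 to 1290.3 ± 83.7 (7.52-fold) and Syt13 at 12.4 ± 6.59 to 149 ± 12 (12-fold). Cell cycle and cholesterol genes were higher as groups, but not with an estimated correlation (adjusted p = 0.174 for G2/M, 0.206 for G1/S and 0.196 for cholesterol).

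The log2 difference was 3.47 for Ptn (SE 0.16, adjusted p = 1.4e-09), 2.91 for Thbs1 (SE 0.10, adjusted p = 3.9e-11), 3.58 for Syt13, 2.77 for Scara5, 2.56 for Rab3il1, 2.31 for Stc1, 2.23 for Col6a2 and 2.15 for Enpp2. It was -6.54 for Ptprc (SE 0.60, adjusted p = 1.6e-06), -6.48 for C3 (SE 0.39, adjusted p = 3.3e-08), -6.43 for Satb1, -5.94 for Traf1 and -5.88 and -5.78 for the lymphocyte genes Gimap4 and Cytip. The genes lower in Th17 held few reads there (means of 5.30 or less on this scale), so the size of their differences depends on the 1 added before the log. All 16 kept their call with each Th9 or Th17 library left out.

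Of 29 lists, 13 passed in Th17 against Th9. T cell transcripts were high in the Th9 libraries and not in the Th17 libraries, and reads of T cells were not set apart for these lists. A list difference therefore cannot be told apart from one in T cell reads. NF-kB and IL-17 targets were lower in 13 of 14 genes (13 adjusted over the list alone; median -1.75, adjusted p = 4.2e-23, and adjusted p = 0.00103 with an estimated correlation), T cell markers in 16 of 18 (18 adjusted over the list alone; -3.48, 4.5e-18) and STAT3 targets in 11 of 13, with 1 higher (-0.83, 1.2e-08). Also lower were p53 targets (8 of 14, with 1 higher; -0.34, 3.4e-05), MHC class I genes (9 of 16, with 1 higher, or 9 and 3 adjusted over the list alone; -0.47, 4.2e-04) and Th1 and effector genes (3 of 3; -4.11, 1.3e-04). For these 5 the adjusted p with an estimated correlation was 0.0475. The remaining calls were lost in that way. They were G2/M genes (17 of 21 higher, 20 adjusted over the list alone; 0.37, adjusted p = 5.6e-10, and adjusted p = 0.174 with an estimated correlation), G1/S genes (10 of 21 higher, 14 adjusted over the list alone; 0.28, 5.5e-07, and 0.206), cholesterol genes (13 of 20 higher; 0.34, 2.8e-06, and 0.196) and histone genes (9 of 18 higher; 0.29, 6.4e-04, and 0.450). Stress response genes (11 of 18 lower and 3 higher, 12 and 4 adjusted over the list alone; -0.78, 1.8e-06, and 0.162), proteases and adhesion genes (10 of 22 lower and 3 higher, 10 and 4 adjusted over the list alone; -0.12, 0.0208, and 0.361) and ribosomal protein genes (3 of 24 lower; -0.18, 0.00686, and 0.473) were lower. The ribosomal call was lost without Th17 replicate 2 (adjusted p = 0.0579). The EMT lists did not pass: of 9 EMT transcription factor genes 3 were lower and 1 higher (-0.12, adjusted p = 0.489), of 21 mesenchymal and matrix genes 8 were higher and 4 lower (median 0.07, mean -0.04, adjusted p = 0.189), and of 10 epithelial genes 4 were higher and none lower (0.37, adjusted p = 0.0652). The mesenchymal mean was below 0 only through its lowest member, at -5.68. The other 13 lists did not pass either.

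Of 14443 genes tested in Th17 against Th9, 1397 were higher and 1621 lower at an adjusted p under 0.05 (limma), 176 and 394 of them by a factor of 2 or more. The groups did not overlap for 44.9% of the genes, where chance gives 10%. With only the Th9 and Th17 libraries in the model the counts were 2332 and 2458, and without Th9 replicate 1 920 genes were higher.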

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

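Of the tests in this part, the scaling test and both tests on receptor genes were chosen only after the result was seen. In the direct test of Th17 against Th9, 13 gene lists and 16 named genes differed, but 7 of the 13 lists did not with an estimated correlation (G2/M, G1/S, cholesterol, histone genes, the stress response, proteases and adhesion genes, and ribosomal proteins). Reads of T cells in the Th9 libraries were not set apart in this test. The median log2 difference, Th17 minus Th9, was -1.75 for NF-kB and IL-17 targets, -3.48 for T cell markers, -4.11 for Th1 and effector genes, -0.83 for STAT3 targets, -0.47 for MHC class I, -0.34 for p53 targets, -0.78 for the stress response, -0.12 for proteases and adhesion genes and -0.18 for ribosomal proteins. It was 0.37 for G2/M, 0.28 for G1/S, 0.34 for cholesterol and 0.29 for histone genes. Among single genes it was 3.58 for Syt13, 3.47 for Ptn, 2.91 for Thbs1, 2.77 for Scara5, 2.56 for Rab3il1, 2.31 for Stc1, 2.23 for Col6a2 and 2.15 for Enpp2. It was -8.07 for Cd3g, -6.54 for Ptprc, -6.48 for C3, -6.43 for Satb1, -6.01 for Ctla4, -5.94 for Traf1, -5.88 for Gimap4 and -5.78 for Cytip.

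The first pattern is the rise of NF-kB and IL-17 targets in Th9, beside the rise of T cell markers in the same libraries. Scaling shifts all genes of a library alike, and the median of all genes was -0.02 to 0.10 under 3 other scalings, against -0.01. Shifts of that size could not account for the list's median log2 fold change of 1.88. The outcome of the scaling test was therefore close to fixed beforehand. The list's median was 1.498 to 1.99 under those scalings (over the members that passed the filter under each). Reads from T cells left in the Th9 libraries cannot be told apart from a change in LLC1 cells. Over the 3 Th9 libraries the median slope of the list on the T cell marker score was 0.349 (SE 0.275), against 0.948 (SE 0.174) for the markers themselves. Each SE measures the spread between genes, 16 and 21 of them. It holds no error from fitting each slope on 3 libraries, so the slopes cannot decide. A response of LLC1 cells to Th9 cells stays open and was not tested on sorted tumour cells alone.

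The second pattern is that many more genes differed between Th17 and Th0 without Th0 replicate 1 (974 higher and 1378 lower, against 170 and 56). A few RNA genes taking many reads are argued against as its whole source: without mt-Rnr1, mt-Rnr2 and Gm26917 the chi-square of that library against the other Th0 libraries was still at least 4.17 times that of the other pair (22.9 and 25.8 against 5.49). With those genes in it was 83.3 and 95.1 against 7.89, so most of the excess of the chi-square went with them. That sum can be led by a few genes with many reads and is not a count of genes called. With the same total without the 3 RNA genes, 447 genes were called over all 6 libraries, far from the count without Th0 replicate 1. GC content and transcript length trends are argued against too, since with them removed per library 225 genes were called over all 6 libraries, against 226 with them left in and 2352 without that library. What sets the library apart stays open, and no biological explanation was tested, since the labels give it no feature of its own.

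The third pattern is T cell transcripts in Th9 with little Cd4. In the 3 Th9 libraries Trdc was at 77 to 145, Tcrg-C2 at 28 to 55, Tcrg-C4 at 15 to 42 and Cd4 at 17 to 23. CD4-positive T cells that passed the sort are argued against as the whole source, since the constant genes of the gamma and delta chains together held at least 4.44 times the value of those of the alpha and beta chains (275 against 62 in Th9 replicate 1), although Trbc1 and Trbc2 can share reads. This comparison was set after these values were seen. The sums were not scaled for transcript length or number of genes, so their ratio is not a share of cells. T cells without CD4 that carry the gamma-delta receptor cannot be told apart from other T cells as the source of the rest: all 4 tested gamma and delta constant genes were called higher in Th9, but those of the alpha and beta chains, which were higher there too, were too low to be tested. Other lymphocytes without CD4 were not tested, and the alpha and beta reads leave a part for them or for CD4-positive cells.

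For counts of calls, other splits of the 6 libraries into 3 and 3 are too few for a share under 0.05 (10 splits, the real one among them as the 1 split with as many calls). The real split called 3653 genes for Th9 against Th0, 226 for Th17 against Th0 and 3018 for Th17 against Th9, and the highest of the other splits 0 in each.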

How the results depend on the processing

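Removal of GC content and length trends and the same total without the 3 RNA genes were chosen only after the data were seen. No called list or named gene changed direction under any setting. The counts of kept calls are over the settings that tested a gene or list. Of 105 called named genes in Th9 against Th0, 92 kept their call under every other setting and 91 with each library left out, in Th17 against Th0 19 and 6 of 34, and in Th17 against Th9 16 and 16 of 16. Of the 105, 94 were tested among genes with a mean of at least 50. Of the called lists, 12 of 14, 1 of 1 and 13 of 13 kept their call under the other settings that tested them, and 14, 1 and 12 with each library left out. Among genes with a mean of at least 50 not all 14 were tested (12 kept their call and 1 lost it). With an estimated correlation 1 list was called in Th9 against Th0 (of 14), 0 in Th17 against Th0 (of 1) and 6 in Th17 against Th9 (of 13). Apart from the total with and without the 3 RNA genes, the cause was not tested for the changes that follow. Fewer samples or fewer genes tested are part of some settings.

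With array weights 3302 genes were higher and 3326 lower in Th9, 1572 and 1789 in Th17, and 1026 and 1283 in both. With the same total per library 794 were lower in Th9, 20 in Th17 and 12 in both. Of the called named genes, 12 in Th9 and 13 in Th17 lost their call with that total. With the 3 RNA genes left out of the total, 1 in Th9 and 1 in Th17 did, so most of these losses went with those 3 genes. With array weights 7 of 12 named genes that were not called in Th9 and 6 of 12 in Th17 gained a call, as did 6 of 11 in Th17 that were chosen after the data were seen. With the same total without the 3 RNA genes 345 were higher and 102 lower in Th17, and 245 and 71 in both. With only the 6 Th9 and Th17 libraries 2332 were higher and 2458 lower in Th17 than Th9. In Th17 4 lists were called with no filter, 3 with array weights and 2 with GC content and length trends removed. Genes that were not called changed sign: in Th9 Zeb1 was at 0.066 with the same total and 0.0027 with the same total without the 3 RNA genes, and Vim at 0.029 with the same total. In Th17 Cd4 was at 0.00499 with the same total, 0.015 with trends removed and 0.00506 without the 3 RNA genes, and Vim at -0.026 with array weights. Of genes chosen after the data were seen, Ighm was at 0.35 with array weights and Ocln at -0.062 with array weights and -0.0092 with trends removed in Th9, and in Th17 Ccl2 was at 0.071 with array weights and Ptpn22 at 0.0015 with the same total.

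With each library left out, genes higher in Th9 ranged from 1015 to 2594 and lower from 838 to 2742. In Th17 they ranged from 14 to 974 and from 2 to 1378, in both from 13 to 573 and from 1 to 967, and genes higher in Th17 than Th9 from 920 to 1033. Lists called in Th17 ranged from 1 to 3. Cdh2 ranged from -0.31 to 0.013 in Th9 and from -0.22 to 0.094 in Th17, Vim from -0.25 to 0.018 and from -0.067 to 0.20, and Cd4 in Th17 from -0.30 to 0.30. Of genes chosen after the data were seen, Ighm ranged from -0.62 to 0.364 and Ocln from -0.136 to 0.20 in Th9. In Th17 Ccl2 ranged from -0.166 to 0.074, Krt18 from -0.212 to 0.051, Tjp1 from -0.028 to 0.17 and Ptpn22 from -0.41 to 0.26. Of such genes that were called, 37 of 46 in Th9 and 0 of 10 in Th17 kept their call with each library left out, and 35 and 2 under every other setting, where a setting tested them. Among genes with a mean of at least 50, only 35 of the 46 and 8 of the 10 were tested. Without Th0 replicate 1, 43 of the 46 and 8 of the 10 were.

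The labels give no pairing of the samples beyond a replicate number, and the values do not settle whether the numbers pair them. Deviations of libraries with the same number correlated at 0.111, -0.0110 and 0.145 across genes in Th9, and at -0.0547, -0.0795 and 0.0390 in Th17, with the own number as best match in 2 of 3 and 1 of 3. With the replicate block 2114 genes were higher and 1962 lower in Th9, 186 and 76 in Th17, 1344 and 1583 in Th17 against Th9, and 141 and 54 in both. Krt18 (Th9) and Ptprc (Th17) gained a call and Herpud1, Slc7a5 and Lig1 (Th17) lost it, and no other named gene and no called list changed its call. The edgeR and DESeq2 alternatives were not run, because the values are not counts. With the same spread in every library and the same dispersion for every gene, simulated changes of the smallest fold were called in 28% to 38% of genes.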

Other observations

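All results in this part were chosen only after the data were seen, and none tests an explanation. T cell receptor genes of the gamma and delta chains stood out in Th9. Tcrg-C1 was at 2, 0 and 1 in Th0 and at 33, 28 and 29 in Th9, and Tcrg-C2 was listed at 0 in all 3 Th0 libraries. Of the alpha and beta chains, Trac averaged 1.33 in Th0 and 11.3 in Th9, and Trbc2 0.667 and 16.7, while Trbc1, listed at 0 in Th0, averaged 17.7. Cd8a, a co-receptor of cytotoxic T cells, was at 7, 6 and 7 in Th9.

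Immunoglobulin genes, which B cells express, were present in Th0 and lower with Th17. Ighm, the constant gene of the mu heavy chain, was at 191, 61 and 48 in Th0 and 75, 68 and 67 in Th9 (log2 fold change -0.24, adjusted p = 0.690). In the table with Th17 it was at 196, 63 and 49 in Th0 and 4, 2 and 2 in Th17. Igkc, the kappa light chain, fell with both T cell types (-2.66, adjusted p = 0.00650, in Th9 and -3.39, adjusted p = 0.0338, in Th17), as did the heavy chain segment Ighv11-2 (-3.78, adjusted p = 0.00257, and -3.26, adjusted p = 0.0410). In Th17 both lost their call without any 1 of the 5 libraries other than Th0 replicate 1 (adjusted p up to 0.143 for Igkc, without Th17 replicate 1, and 0.125 for Ighv11-2, without Th17 replicate 2), and Ighv11-2 with 0.5 added before the log (0.0526). Lyz2, lysozyme of myeloid cells, fell in Th9 (-3.36). Th0 replicate 1 held the highest Ighm value of the Th0 libraries.

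Among 273 KEGG pathways in Th9 against Th0, 66 passed as higher and 5 as lower, and 0 with an estimated correlation. Cytokine-cytokine receptor interaction had 46 of 98 genes higher and 6 lower (adjusted p = 2.9e-07, and adjusted p = 0.510 with an estimated correlation), and TNF signaling 35 of 88 higher and 9 lower (1.9e-05, and 0.828). Biosynthesis of amino acids had 22 of 57 genes higher and 1 lower (3.2e-05, and 0.828). Lower were the spliceosome (2 of 123 higher and 25 lower; 0.00155, and 0.894), DNA replication (2 of 35 higher and 12 lower; 0.00280, and 0.828), mismatch repair (2 of 22 higher and 8 lower; 0.00930, and 0.828), homologous recombination (2 of 27 higher and 7 lower; 0.0156, and 0.714) and base excision repair (2 of 32 higher and 9 lower; 0.0397, and 0.753). Cell cycle, with 20 of 117 genes higher and 30 lower, did not pass (0.0902, and 0.920). Among 268 pathways in Th17 against Th0, steroid biosynthesis (3 of 16 higher, none lower; adjusted p = 0.00872) and N-glycan biosynthesis (4 of 43 higher, none lower; 0.0318) passed, both at an adjusted p of 0.995 with an estimated correlation. T cell receptor signaling, with 40 of 87 genes higher and 6 lower in Th9 (2.9e-07, and 0.714), moved with the T cell markers.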
